A study of Mus musculus with 4 samples.

How the data were processed

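RNA from 4 mouse embryonic stem cell (ESC) lines was measured on Agilent whole-genome 4 x 44K arrays in the one-colour format, with Cy3 as the label. Per the labels, 2 lines were wild type and 2 were deficient for Dppa2 (also called ECAT15-2). Lines were put into groups by their titles. The WT 1 and KO 1 lines came from blastocysts of mother 1046, and the WT 2 and KO 2 lines from blastocysts of mother 875, so the replicate number marks a shared mother. The 4 lines are separate derivations with 1 array each.

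The intensity values of the spots were extracted from the scanned images with Agilent Feature Extraction 10.7.3.1, per the file headers, which record that the processed intensity is already background-subtracted and detrended within each array and not yet scaled between arrays. The median spot intensity and the local background intensity are raw values, per the file headers. The deposited series table holds log2 values, and its scale was read from the values because the sources used here do not state it: each column correlated with log2 of the processed signal of its array at 0.999899 to 0.999986, all 4 columns shared their quantiles within 0.000727, and each had a median of 6.55, so the deposited log2 values are quantile-normalized and not centred per gene. GeneSpring GX11 is named for the study's own analysis, per the labels. The array annotation in the file headers refers to genome build mm9, whereas gene symbols were taken from a RefSeq table of assembly GRCm38.p6, so no coordinates are given and chromosomes follow that table.

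The main values were log2 of the processed signal minus the 75th percentile of each array, re-centred on the mean percentile so that they read as log2 signal. Control spots and spots with an outlier flag were left out, and spots of the same probe were averaged. Of 41174 gene probes, 26690 matched 1 symbol through their accession, 0 matched several and 14484 matched none and kept their accession. A probe was kept where the scanner software called it well above background on both arrays of at least 1 group, and the brightest such probe stood for its gene, which left 21639 genes and transcripts, 14372 of them with a symbol. Another 233 probes had an outlier flag on every spot of an array and were left out.

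The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. The main model held genotype alone, and a model with the mother as a block was fitted beside it because the labels tie equal numbers to a shared mother. The differences between the mothers correlated at 0.19 across genes in the 2 genotypes. All 4 arrays lay on 1 slide and were scanned in 1 scan, so no slide or scan batch was there to test. Changes of at least 2-fold within both mothers' pairs were counted without a test. Where a gene was not well above background on any array of a group, the change is given as "at least N-fold", from the mean of the brighter group against the mean, per array, of the higher of the probe's own value and the lowest signal among probes well above background (log2 3.24 to 3.58).

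Gene lists were fixed before the data were examined, as were the tests, the other settings to try and the rule for named genes. Named genes are Dppa2, Dppa4, Nkx2-5 and Syce1, the 15 largest rises and 15 largest falls among genes with a symbol, an adjusted p under 0.05 and the same direction in both pairs, and up to 4 tested members of each list with the smallest p. Some genes that this rule names are not reported here. Of 21 lists, 18 had at least 5 tested genes. They cover the 2-cell-stage program, germline and meiosis, pluripotency, primed epiblast, primitive endoderm, mesoderm and heart, neural ectoderm, trophoblast, Hox genes, lung, DNA methylation machinery, imprinted genes, fibroblast markers, p53 targets, glycolysis and hypoxia, cholesterol synthesis, interferon response, and heat shock with the unfolded protein response, and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry, and 10000 random lists matched on mean signal served as alternatives. The targeted locus (Dppa2, Dppa4), the genes known to have been followed up by the study (Nkx2-5, Syce1) and the Y-linked genes with Xist have fewer tested genes and were read gene by gene.

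The procedure was tested on simulated data with the spread of these arrays. Of 200 changed genes in each of 20 draws of 21639 genes, 0% were recovered at a true log2 change of 1, 7.16% at 2 and 71.1% at 4, and 4.61% of the calls were false. Lists of 25 genes shifted by 1 on the log2 scale were called in 20 of 20 draws, and unshifted lists in 0 of 360 tests. Simulated genes were drawn independently of each other, so these rates do not cover lists whose members vary together. Noise was drawn from the same normal model and spread that limma fits, with no background floor and no mother effect. The 4.61% of false calls therefore holds under the procedure's own assumptions and does not measure false calls in these arrays. The number of arrays limits the precision: small changes go uncalled at this size.

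Alternatives covered the mother block, quantile and median scaling, normexp background correction with an offset of 50, the deposited log2 values, the filter on dim probes, the rule for several probes, an intensity trend with a robust prior, a plain t statistic, flagged spots kept, each array left out in turn, and genes within 20 Mb of Dppa2 left out. The normexp correction used the median spot intensity, because the files used here hold no mean spot intensity column. Leaving out genes of chromosomes X and Y, or of chromosome 8, was added after the data had been seen. Among 58 called genes with several tested probes, all probes had the same sign for 55, and some probe went the opposite way for 3.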

Results

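A total of 4 ESC lines were profiled, 2 wild type (WT) and 2 lacking Dppa2 (KO), with 1 array per line. Dppa2 encodes a SAP-domain nuclear protein of pluripotent cells and lies next to its paralogue Dppa4 on chromosome 16. The lines were grown for 3 days on gelatin with LIF and 15% fetal calf serum. The KO lines also carried a conditional targeted allele of Dppa4 on both copies, which the WT lines did not, so the comparison is between these compound genotypes. Between 28224 and 28989 of 41174 probes (68.5% to 70.4%) were well above background on each array, and no spot was saturated. The 2 WT arrays correlated at 0.989 across genes and the 2 KO arrays at 0.983, against 0.955 to 0.970 between genotypes; genes are not independent replicates.

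Dppa2 was measured at 12.09 and 12.03 log2 signal in the WT lines and at 7.05 and 7.12 in the KO lines, a 31.4-fold fall (log2 change -4.97, SE 0.12, n = 2 per group, limma adjusted p = 0.0089). Its only probe stayed well above background in both KO lines, and where it lies relative to the deleted part is not given in the sources used here. Dppa4 had means of 13.45 ± 0.12 (SD, n = 2) in WT and 14.01 ± 0.08 (SD, n = 2) in KO lines, a log2 difference of 0.55 (SE 0.14) that did not pass the test (limma adjusted p = 0.154). Adjusted over the list alone, that is over these 2 genes, Dppa2 was lower and Dppa4 higher. Over 2 genes the adjustment leaves the larger p unchanged, so Dppa4 passed there at its unadjusted p (limma, 0.0204). With the mother as a block, Dppa2 kept its value but not its call (limma adjusted p = 0.0790), as it did without WT replicate 1 (0.140), WT replicate 2 (0.149) or KO replicate 2 (0.0654); its log2 change stayed between -5.01 and -4.37 over all alternatives.

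**Figure D1:**
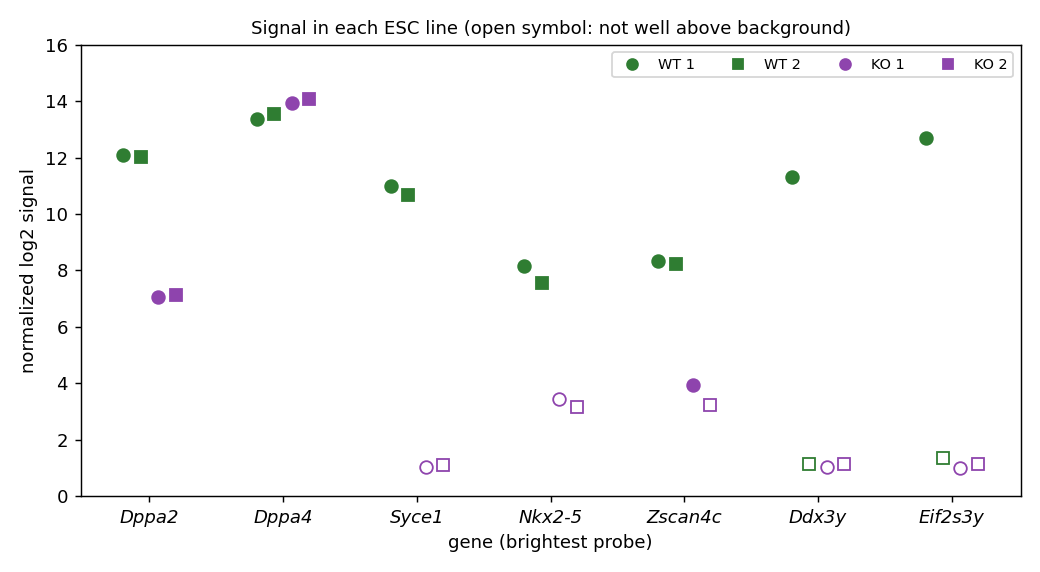
Normalized log2 signal of the brightest probe of 7 genes in each of the 4 ESC lines, with circles for lines of mother 1046 and squares for mother 875; open symbols are not well above background. Dppa2 lies near 12.06 in both WT lines and near 7.09 in both KO lines, and the Y-linked genes Ddx3y and Eif2s3y have signal in the WT 1 line but not in the other 3.

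Across the genome the question was which genes depend on the genotype. The calls were mostly falls: 361 genes and transcripts fell and 38 rose in the KO lines out of 21639 tested by limma, so 90.5% of the calls were lower. The largest fall was that of Reg2, a secreted C-type lectin protein, from a mean of 11.52 to a level not well above background, at least 302-fold. Syce1, a component of the synaptonemal complex, fell at least 187-fold, and Afm, an albumin family gene, at least 79.8-fold. Nkx2-5, a cardiac homeobox gene, fell at least 22.2-fold. Syce1 and Nkx2-5 are genes the study is known to have followed up, and both fell (2 lower when adjusted over the list alone). As they were chosen on these samples, this is not independent evidence.

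Other large falls were those of the cathepsin gene Ctsh (at least 73.1-fold), Tescl (at least 47.9-fold), Fam162b (at least 45.0-fold), Kcne1l (at least 36.6-fold), Cdcp1 (at least 24.5-fold) and Ecrg4 (at least 18.4-fold). Alox5, the gene of arachidonate 5-lipoxygenase, fell 98.5-fold and the carbonic anhydrase gene Car4 fell 91.1-fold, each with 1 of 2 KO arrays well above background. Of the 361 falls, 163 concerned genes not well above background on either KO array. For the large falls named above, from Reg2 to Car4, limma adjusted p lay between 0.00682 and 0.0326. Where neither KO array was well above background, these p rest on a KO spread of background signal, with SDs of 0.08 for Reg2 and 0.07 for Syce1. That spread does not measure how expression varies between KO lines, which holds for all 163 such falls.

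The rises were smaller. Wfdc15a rose 14.7-fold (log2 change 3.88, SE 0.40, n = 2 per group, limma adjusted p = 0.0497) and the homeobox gene Dmbx1 rose as well (log2 change 3.43, SE 0.30, n = 2 per group, limma adjusted p = 0.0388). Mag, which encodes myelin-associated glycoprotein, rose 8.36-fold, the lysosomal membrane gene Laptm5 5.62-fold, the RNA sensor gene Ddx58 3.73-fold, the thrombopoietin gene Thpo 3.64-fold, the signalling ligand gene Wnt3a 3.51-fold and the cholesterol exporter gene Abca1 3.39-fold. Another 6 of the 15 largest rises started from WT levels not well above background and are bounds: 2610028E06Rik rose at least 7.68-fold, Vmn1r236 at least 2.04-fold, Resp18 at least 1.90-fold, Slc22a26 at least 1.36-fold, C1s2 at least 1.34-fold and the GATA factor gene Gata5 at least 1.13-fold. Pnmal2 was also called higher, but its mean on the KO arrays lay below the mean floor of the WT arrays. No bound can therefore be given for it, and its log2 difference turned to -0.055 under normexp background correction. In all, 13 rises concerned genes not well above background on either WT array. Their p rest on a WT spread of background signal, which does not measure how expression varies between WT lines.

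Within the pairs of lines from the same mother, 1502 genes were at least 2-fold lower and 337 at least 2-fold higher in both pairs, a count with no test that dropped to 681 and 135 under normexp background correction. The corresponding count by mother, at least 2-fold the same way within both genotypes, was 249, and differences of opposite sign in the 2 genotypes numbered 76. These counts are not on equal terms, since the filter on dim probes works by genotype group. A gene at background in both KO lines stays in, while a gene at background in both lines of 1 mother is left out. The differences of the 2 pairs correlated at 0.71 across genes. At an unadjusted p under 0.05, limma gave 2687 lower and 2412 higher, and the direction of this excess turned under quantile scaling (2423 lower, 3048 higher), normexp with quantiles (2547 and 2838), the deposited values (2467 and 2893) and median centring (2078 and 4906). On the main scaling the direction also turned with an intensity trend and robust prior (2724 lower, 2942 higher). The median over all tested genes was 0.10 on the log2 scale, and 0.26 under median centring, against which the changes of gene groups are to be read.

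With the mother as a block, limma called 0 genes in either direction (2736 lower and 2278 higher at an unadjusted p under 0.05, smallest adjusted p 0.0790), and a plain t statistic with adjustment also called 0 (1635 lower and 2264 higher unadjusted). With genes required to be above background on all 4 arrays limma also called 0 (2184 lower and 2444 higher unadjusted, smallest adjusted p 0.0503). Leaving out WT replicate 1, WT replicate 2 or KO replicate 2 left 0 calls, while leaving out KO replicate 1 gave 679 lower and 64 higher.

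**Figure D2:**
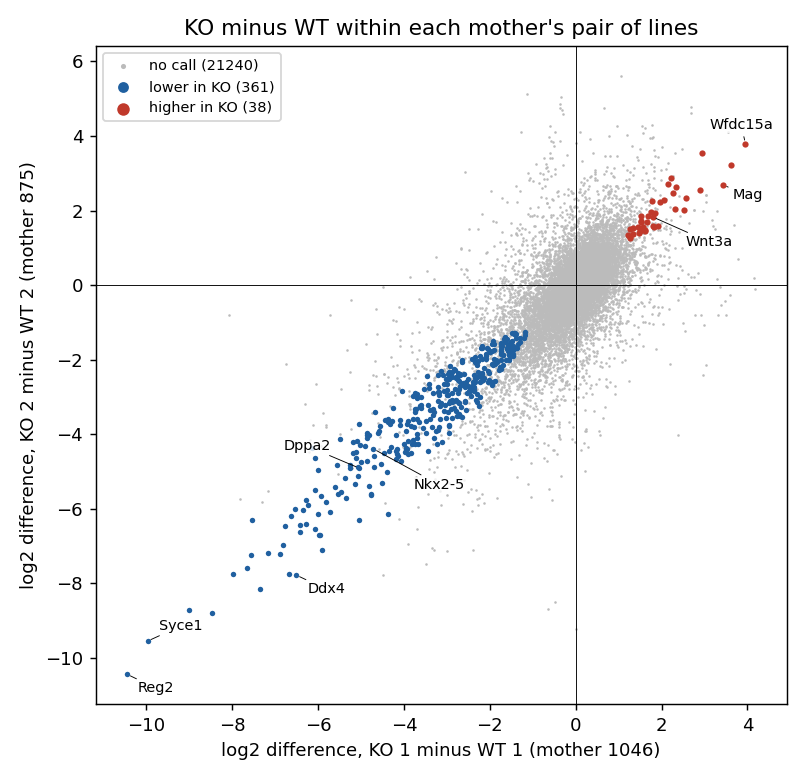
Log2 difference of KO minus WT for 21639 genes and transcripts, in the pair from mother 1046 (x axis) and in the pair from mother 875 (y axis), each point 1 gene and colours marking limma calls. The 361 falls (blue) reach -10.44 on both axes, at Reg2, and the 38 rises (red) reach 3.95 and 3.80, at Wfdc15a.

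Genes of the germline and of meiosis were the list with the most falls. Of 33 tested members, 12 fell, 0 rose and 21 did not pass (18 fell when adjusted over the list alone). Besides Syce1, these were genes such as Ddx4, the vasa helicase gene, which fell 141-fold from 11.74 ± 0.11 to 4.60 ± 1.01 (SD, n = 2 each), Mael, a piRNA pathway gene, which fell 132-fold with 1 of 2 KO arrays above background, Taf7l (at least 43.7-fold), the RNA-binding protein gene Dazl (at least 15.8-fold) and Fkbp6 (at least 12.3-fold). The median log2 change was -1.39, or -0.87 with dim genes at their bound, and limma's camera gave an adjusted p of 3.2e-09. The median was smaller with genes above background on all 4 arrays (-0.26), under normexp with the 75th percentile (-0.64) or quantiles (-0.50), with no filter on dim probes (-0.86) and without genes of chromosomes X and Y (-0.87). The call was lost with an estimated correlation (adjusted p = 0.326 with an estimated correlation). Syce1, chosen on these samples, is among the 12 and enters the median and the camera p. The list was not tested without it.

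Genes of the program that marks the 2-cell embryo and rare ESCs resembling it were also lower. Of 10 tested members, 4 fell, 0 rose and 6 did not pass (5 fell when adjusted over the list alone), with a median log2 change of -2.20, or -1.72 with dim genes at their bound, and a camera adjusted p of 2.7e-05 (limma; adjusted p = 0.389 with an estimated correlation). Zscan4c fell 26.0-fold with 1 of 2 KO arrays above background, Gm428 at least 17.1-fold, Sp110 10.6-fold and the deubiquitinase gene Usp17la 6.41-fold. Only 17 of the 41 listed genes had a probe with that symbol, and the median was -0.62 with no filter on dim probes and -0.86 and -0.66 under normexp with the 75th percentile and quantiles.

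The pluripotency list went the other way as a group. None of its 30 tested members passed the test over all genes, 14 were higher when adjusted over the list alone, and 28 of 30 had a positive difference. Its median log2 difference was 0.71, or 0.61 above the median of all genes, and limma's camera gave an adjusted p of 4.8e-07 (adjusted p = 0.389 with an estimated correlation). The members with the smallest p were Eras, with a log2 difference of 1.30, Nr0b1 with 1.93, Dnmt3l with 1.37 and Tfcp2l1 with 1.32. Limma adjusted p lay between 0.0602 and 0.0859 for these 4.

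Trophoblast and Hox genes were lower as groups. Of 22 trophoblast genes, 1 fell, 0 rose and 21 did not pass (11 lower and 1 higher when adjusted over the list alone), with a median log2 change of -1.29 and a camera adjusted p of 8.4e-06 (limma; adjusted p = 0.389 with an estimated correlation). The median was -0.71 and -0.60 under normexp with the 75th percentile and quantiles. The member that fell was Krt8, a keratin of simple epithelia (6.72-fold, limma adjusted p = 0.0497), and Hand1, with a log2 difference of -4.75, just missed the threshold (limma adjusted p = 0.0505). Of 26 Hox genes none passed (2 lower when adjusted over the list alone), and the median difference was -1.10 relative to the median of all genes (camera in limma, adjusted p = 9.4e-05; adjusted p = 0.517 with an estimated correlation). That median before subtraction went to -0.57 without WT replicate 1, to -1.70 without WT replicate 2, and to -0.53 and -0.33 under normexp with the 75th percentile and quantiles. Hoxd13 had a log2 difference of -0.95, and Hoxb1, not above background in the KO lines, differed at least 2.67-fold without passing.

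Of 31 mesoderm and heart genes, 2 fell, 0 rose and 29 did not pass (4 lower and 1 higher when adjusted over the list alone). These were Mesp2, a transcription factor gene of early mesoderm, which fell 7.03-fold, and Nkx2-5. As Nkx2-5 was chosen on these samples and enters the median and the camera p, the list is not independent of it. The list was not tested without Nkx2-5. The list's median was -0.54, with a camera adjusted p of 0.0014 (limma; adjusted p = 0.517 with an estimated correlation). Of 22 fibroblast genes, which mark feeder or stromal cells, 2 fell and 20 did not pass (3 lower when adjusted over the list alone): the gelatinase gene Mmp2 fell 10.8-fold and the fibrillin gene Fbn1 7.07-fold. The fibroblast median was -0.58, with a camera adjusted p of 0.0015 (limma; adjusted p = 0.517 with an estimated correlation). It was -1.18 in the pair of mother 1046 and -0.12 in that of mother 875. The WT lines themselves differed here: the median of WT 2 minus WT 1 was -1.11 for fibroblast, -1.10 for Hox and -0.68 for mesoderm genes. Without WT replicate 1, neither the mesoderm nor the fibroblast list was called (limma camera adjusted p of 0.0684 and 0.371, the highest over their 19 alternatives, with lowest values of 5.5e-06 and 2.9e-09). The fibroblast median was then -0.11, and without WT replicate 2 the medians were -0.97 for mesoderm and -1.43 for fibroblast genes. Under normexp with quantiles they were -0.29 and -0.36.

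Of 25 primitive endoderm genes, 2 fell, 1 rose and 22 did not pass (10 lower and 3 higher when adjusted over the list alone). The endocytic receptor gene Lrp2 fell 5.27-fold and its adaptor gene Dab2 fell 3.37-fold, whereas the laminin gene Lama1 rose 3.21-fold. The median was -0.43 (limma camera adjusted p = 0.0331; adjusted p = 0.517 with an estimated correlation), and this was the list that the mother block moved past the threshold (limma camera adjusted p = 0.0604, between 0.00546 and 0.2004 over 19 alternatives). It was not called under 9 of these, the others being WT replicate 1 (0.166, median -0.034), KO replicate 1 (0.0540) or KO replicate 2 (0.133, median -0.27) left out, quantile scaling (0.0638, median -0.17), the deposited values (0.0710, median -0.19), no filter on dim probes (median -0.14), and genes of chromosome 8 (0.188, median -0.13) or of X and Y (0.0537, median -0.29) left out. Its median was also smaller under median centring (-0.26) and normexp with quantiles (-0.10). Of 19 primed epiblast genes, 1 fell, the transcription factor gene Sox4 (2.92-fold), and 18 did not pass (5 lower and 1 higher when adjusted over the list alone). That list's median was -0.43 (limma camera adjusted p = 0.0074; adjusted p = 0.389 with an estimated correlation), and -0.90 and -0.28 without KO replicate 1 and KO replicate 2, -0.26 under median centring and -0.28 under normexp with the 75th percentile. Fgf5, a growth factor of the primed epiblast, had a log2 difference of -3.40 (limma adjusted p = 0.0584).

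Cholesterol synthesis genes had a small positive median of 0.34, or 0.24 above that of all genes, with 22 of 25 positive. In limma 0 members rose, 1 fell and 24 did not pass (1 lower when adjusted over the list alone). Limma's camera gave an adjusted p of 0.0187 for the list (adjusted p = 0.675 with an estimated correlation), a call lost under 6 of 19 alternatives, with 3.1e-04 as the lowest value over them. These were quantile scaling (0.133), normexp with quantiles (0.0754), the deposited values (0.129), every probe taken separately (0.0677), and WT replicate 1 (0.371, median 0.16) or KO replicate 2 (0.129) left out.

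**Figure D3:**
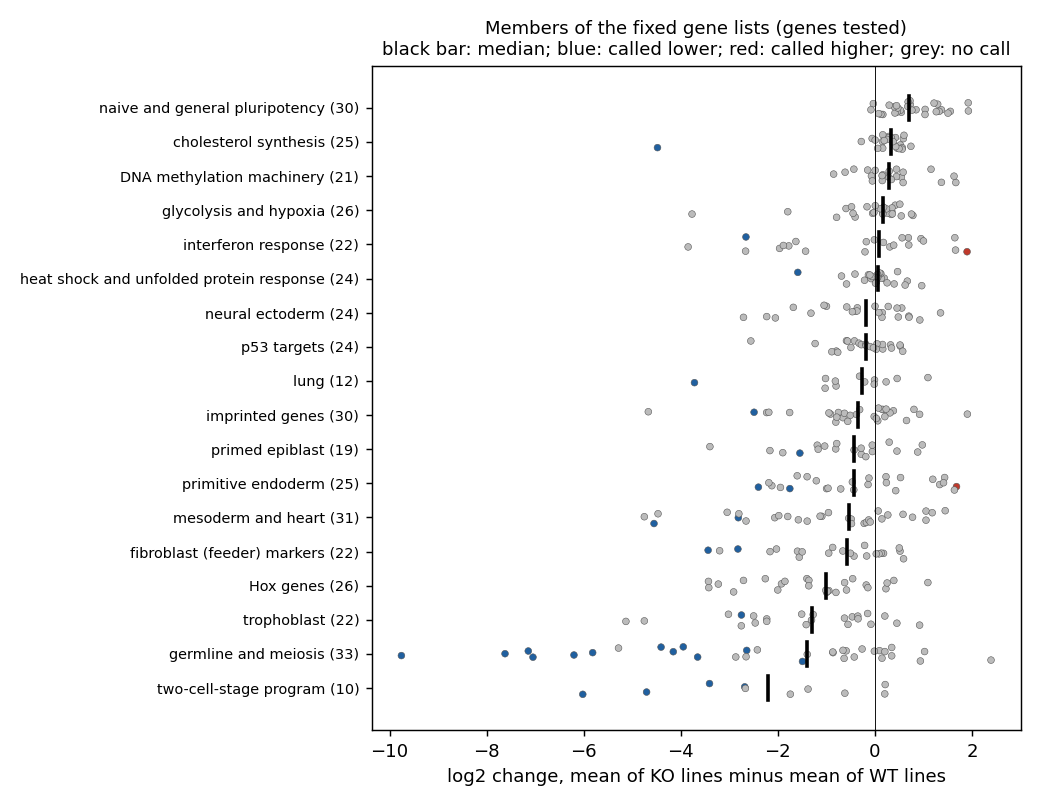
Log2 change (mean of the 2 KO lines minus mean of the 2 WT lines) of each tested member of 18 gene lists, with black bars at the medians and colours for limma calls. Medians run from -2.20 for the 2-cell-stage list to 0.71 for the pluripotency list.

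In all, limma's camera called 10 of 18 lists, 8 lower and 2 higher, and 9 with the mother block. With an estimated correlation it called 0 of 18 (1 at an unadjusted p under 0.05, germline and meiosis, with 0.0181), while limma's fry called 2 as moving in 1 direction, germline and meiosis and the 2-cell-stage list. The 8 lists that were not called had small medians: -0.18 for neural ectoderm, -0.26 for lung, 0.29 for the DNA methylation machinery, -0.35 for imprinted genes, -0.18 for p53 targets, 0.16 for glycolysis and hypoxia, 0.08 for the interferon response and 0.06 for heat shock and the unfolded protein response. Their limma camera adjusted p lay between 0.0571 for lung and 0.869 for heat shock. Over 19 alternatives the median ranged from -0.53 to -0.09 for lung, -0.49 to 0.17 for neural ectoderm and -0.47 to -0.10 for imprinted genes. It ranged from -0.31 to -0.01 for p53 targets and from 0.16 to 0.46 for the DNA methylation machinery. Of 19 alternatives, 5 called the imprinted genes (among them quantile scaling, 0.0214, and leaving out KO replicate 1, 0.0122), 4 the p53 targets (quantile scaling, 0.0116), 4 the lung list (among them leaving out WT replicate 1, 0.0377) and 2 the DNA methylation list. Single members did pass in some of them. Cftr, the chloride channel gene on the lung list, fell at least 8.67-fold, the imprinted gene Asb4 5.61-fold and the stress-induced transcription factor gene Atf3 3.00-fold; each was also the only member of its list to pass when adjusted over the list alone. On the interferon list Isg15, a ubiquitin-like modifier gene, fell 6.30-fold while Ddx58 rose 3.73-fold (6 lower and 3 higher when adjusted over the list alone), and the median of the list, which turned negative under normexp with the 75th percentile (-0.013), differed in sign from its mean (-0.37). The glycolysis list also had a mean (-0.11) opposite in sign to its median, and the heat shock list had a downward direction in camera beside its positive median, which turned negative under quantile scaling (-0.079). Adjusted over the list alone, 2 neural ectoderm genes were lower, 3 DNA methylation genes were higher, and no gene of the glycolysis or p53 lists passed.

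The lines of the 2 mothers were compared to describe differences that genotype does not explain. Limma called 0 genes for the mother in a model with genotype (1611 at an unadjusted p under 0.05, smallest adjusted p 0.665). That model also called 0 genes for genotype (smallest limma adjusted p 0.0790), so its calls cannot rank mother against genotype. The filter on dim probes, which works by genotype group, also leaves out genes at background in both lines of 1 mother. Single genes did differ between lines: among sex-linked genes, Ddx3y, a Y-linked RNA helicase gene, had 11.33 log2 signal in the WT 1 line and at most 1.16 in the other 3, where it was not well above background. Xist had 3.89 ± 0.33 (SD, n = 2) in WT and 4.62 ± 1.27 (SD, n = 2) in KO lines (limma adjusted p = 0.541), a difference of 0.73 that turned to -0.17 without KO replicate 2. Tsix (log2 difference 0.95) and the Y-linked gene Zfy2 (-0.74) did not pass either, so that 0 of 3 tested members of this list passed, also when adjusted over the list alone.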

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

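The tests on signal near background, on an even loss of differentiated cells, on feeder fibroblasts, on intensity-dependent bias and on the sex chromosomes were chosen only after their results, or an earlier form of the test, had been seen. Those on scaling and on chromosome 8 copies were written down first. The background and cell-type tests were revised more than once after values had been seen: the background test first had 0 calls to read and then split genes by a mean signal that a fall itself lowers, and the cell-type tests first set 1 list against the other without left-out arrays or the second pair.

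Signal of 4 Y-linked genes that were not among those tested appeared on 1 array, whereas the Y-linked gene Zfy2 was above background on all 4 with 1 of its 2 probes. On the WT 1 array Ddx3y had 11.33, Eif2s3y 12.69, Kdm5d 4.06 and Uty 6.57 log2 signal, all well above background, against at most 1.16, 1.35, 1.38 and 1.31 on the other 3 arrays, none of which was above background.

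The calls were mostly lower in the KO lines, 90.5% of 399. For the calls, scaling between the arrays is argued against as the whole cause, since their lower share was 84.2% or more under 5 other scalings. The deposited values, among these 5, are quantile-normalized too. The argument covers only the calls, all of at least 1.22 on the log2 scale in the main fit. At an unadjusted p under 0.05 in limma, higher genes outnumbered lower ones under quantile scaling, normexp with quantiles, the deposited values and median centring. Whether noise of probes near background adds to the lower share stays open. With every value raised to its array's background floor, 91.1% of the 361 lower calls (95% exact interval 87.7% to 93.9%) were still at least 2-fold lower in both pairs, as were 26 of the 38 higher calls in their direction. With the floor raised 2-fold, 272 lower and 25 higher calls still were. These calls were picked for large changes in the same values, so the test shows only that most do not rest on signal below the floor. Among 10819 genes of brighter mean signal, which a fall itself lowers, 37 calls were lower and 11 higher. With genes required to be above background on all 4 arrays, limma called 0 (2184 lower and 2444 higher at an unadjusted p under 0.05). The genotype stays open, which may act through the absence of Dppa2 or through the conditional targeted Dppa4 allele that the KO lines carry as well, as do differences between single lines.

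Markers of several differentiated cell types were lower in the KO lines while pluripotency genes were higher as a group, calls that were lost with an estimated correlation (0 of 18 lists). An even loss of differentiated cells of every kind stays open: the neural ectoderm median lay 1.11 above the trophoblast median on the log2 scale (95% interval from a bootstrap over genes 0.01 to 2.30), but the interval included 0 without WT replicate 2 (-0.46 to 1.83) and without KO replicate 1 (-0.39 to 1.53), and neural genes went both ways. These intervals, and those for fibroblast genes below, measure the spread among genes of a list, not between lines. Fewer feeder fibroblasts stay open too, since the fibroblast median lay 0.96 above the trophoblast median in the pair of mother 875 (interval 0.08 to 2.02) but matched it in that of mother 1046 (-0.01, interval -1.24 to 1.13). Mmp2 and Fbn1, with means of 10.73 and 8.25 in WT lines, were lower in both pairs (-3.24 and -2.64 in that of mother 875), while the labels put the lines on gelatin. A loss of some kinds of differentiating cells, a change of these genes within ESCs and the genotype may each account for the pattern, and no test here separates them.

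Chromosome 8 genes were higher in the WT 2 line than in the WT 1 line, with a median log2 difference of 0.43 over 750 genes, against -0.04 to 0.03 for the other autosomes, and higher in the KO 2 line than in the KO 1 line (0.18, against -0.05 to 0.02). An extra copy of chromosome 8 in all or part of the WT 2 culture is a candidate explanation: the chromosome's genes, taken in order in segments of 75 genes, had medians of 0.37 to 0.51, where 3 copies against 2 would give 0.58. Intensity-dependent bias is argued against, since 0% of 10000 gene sets matched on signal reached that median. The Y-linked difference, whether from sex or a lost Y chromosome, is argued against as the source of the lower genes, since 74.5% of the 2016 genes at least 2-fold lower in the pair of mother 1046 were also lower in that of mother 875 (12.9% of all tested genes were). Sex and karyotype are not in the labels. Leaving out genes of chromosome 8, or of X and Y, gave 345 and 335 lower calls. That removes only the genes on these chromosomes, so it cannot show whether such a difference between lines changes genes elsewhere.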

How the results depend on the processing

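Leaving out genes of chromosomes X and Y, or of chromosome 8, was chosen after seeing the data; the other alternatives were not. Under the 5 other scalings and background corrections, 397 to 399 of the 399 called genes kept their sign, 206 to 341 stayed called, and 84.2% to 88.8% of the calls were lower. With the mother as a block limma called 0 higher and 0 lower, as did the filter for signal on all 4 arrays (0 and 0) and the plain t statistic with adjustment (0 and 0), which gave 2264 higher and 1635 lower unadjusted. Higher calls numbered 69 under normexp with the 75th percentile, 10 with no filter, which tests more genes, and 80 with a trend and robust prior. Leaving out 1 array gave 0 to 64 higher and 0 to 679 lower; the lone array left is then assumed to vary like the other group. Genes at least 2-fold higher in both pairs numbered 556 under median centring, which raises the median of all genes to 0.26, and 135 and 142 under normexp with the 75th percentile and quantiles. Those at least 2-fold lower numbered 681 and 605 under the same normexp settings and 928 above background on all 4 arrays. A 1.5-fold threshold gave 1199 and 2442 and a 4-fold threshold 31 and 587.

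Dppa2 stayed at -4.97 but missed the threshold with the block (limma adjusted p = 0.0790), the all-array filter (0.0503) and the plain adjusted statistic (0.156); without 1 array it lay between -5.01 and -4.94. Among tests over all genes, Dppa4 (0.55) passed with the plain unadjusted statistic alone. The difference of Pnmal2 reversed under normexp with the 75th percentile (-0.055). That of Xist reversed with a mean of its probes (-0.48) and ranged from -0.17 to 1.63 without 1 array. The estimated correlation called 0 lists, fry 2 by direction and 17 in either direction, 13 medians lay outside 95% of the matched random lists (the 10 called and DNA methylation, imprinted and p53), and the block changed no list call but that of primitive endoderm. The neural ectoderm median reversed with the all-array filter (0.043), a mean of probes (0.076) and every probe separately (0.043), and ranged from -0.49 to 0.17 without 1 array. The interferon median reversed under normexp with the 75th percentile (-0.013), with no filter (-0.093) and without chromosome 8 genes (-0.010), and ranged from -0.15 to 0.23 without 1 array. The heat shock median reversed under quantile scaling (-0.079), normexp with quantiles (-0.082) and the deposited values (-0.058), and ranged from -0.050 to 0.13 without 1 array. Where no construction is named, the cause was not tested. Signal over background limits changes of dim genes to bounds: 163 of the lower calls have no signal above background in the KO lines. A slide block was not run, as all 4 arrays share 1 slide, nor were left-out arrays and the block for the 2-fold counts and the mother comparison, nor the plain statistic for lists.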

Other observations

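The gene families, the chromosomes and the region around Dppa2 were read for groups of lower genes, and these exact tests were chosen only after the results had been seen. They count genes as independent, although all genes were measured in the same 4 lines and may vary together. Their p-values therefore do not measure variation between lines. Families were taken as all 260 symbol stems with at least 8 tested genes, and 2 passed Fisher's exact test with adjustment over them, Wnt and Krt. Of 17 tested Wnt genes, which encode secreted signalling ligands, 10 were at least 2-fold lower in both pairs, 58.8% against 7.92% of other genes (Fisher's exact test, adjusted p = 3.0e-05). Limma called 3 lower and 1 higher: Wnt6 fell by 3.04 and Wnt10a fell by 2.85 on the log2 scale, Wnt2 fell at least 6.47-fold, and Wnt3a rose 3.51-fold. The family median was -1.57, and between -1.53 and -0.77 under the 5 other scalings, with 5 to 10 members at least 2-fold lower. Wnt3, Wnt5a, Wnt7b and Wnt8a are also members of the lists fixed beforehand, so this family is not fully separate from them. Among these, Wnt3 alone was at least 2-fold lower in both pairs (-2.16 and -3.44).

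Of 23 tested keratin genes, which encode the intermediate filaments of epithelia, 11 were at least 2-fold lower in both pairs, 47.8% against 7.92% of other genes (Fisher's exact test, adjusted p = 5.7e-05). Krt8 fell 6.72-fold, Krt13 fell by 2.60 on the log2 scale and Krt12 fell at least 4.24-fold, and the other 20 did not pass in limma. The family median was -1.32, and between -1.15 and -0.33 under the 5 other scalings, with 7 to 11 members at least 2-fold lower. Krt7, Krt8, Krt18 and Krt19 are also members of the lists fixed beforehand, so this family is not separate from them.

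Of 706 tested genes on chromosome 6, 32 were called lower, 4.53% against 1.83% elsewhere (Fisher's exact test, adjusted over 20 chromosomes, p = 1.9e-04). Among genes at least 2-fold lower in both pairs, chromosome 6 (11.6% against 7.79% elsewhere, adjusted p = 0.0119) and chromosome 1 (10.6% against 7.82%, adjusted p = 0.0406) held more and chromosome 4 fewer (5.59% against 8.14%, adjusted p = 0.0406) by Fisher's exact test. Within 20 Mb of Dppa2 on chromosome 16, 4 of 163 tested genes were called, 2.45% against 1.84% elsewhere (Fisher's exact test, p = 0.548). The 4 include the targeted gene Dppa2 itself, and the test was not run without it.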
